A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

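Transcript levels were measured with the Affymetrix Rice Genome Array, a short-oligonucleotide array on which a probe set stands for a transcript. Total RNA came from the lowest 5 mm of the shoot of wild-type rice and of plants homozygous for the gs1;2 mutation, which lack cytosolic glutamine synthetase 1;2, both of the cultivar Nipponbare. Plants grew in hydroponic culture with 1 mM ammonium as the nitrogen source for 7 or 11 d. Genotype and age make 4 groups of 3 arrays, 12 arrays in all, and the submitters' design text calls the arrays of a group biological replicates.

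The deposited values are log2 signals made by robust multi-array averaging (RMA), in R 3.1.0, per the submitters' processing notes. The background correction, the summary options and whether all arrays were processed in a single run are not given in the sources used here. The deposited table holds 57381 probe sets without missing values, and per-array medians lay between 4.944 and 5.005 (log2), so no further normalization was applied. After 187 control probe sets were left out, 57194 probe sets were tested. Scanner files and detection calls were not used here, so signal over background is unknown for each probe set, and the number of arrays limits the precision of every value. No pair of arrays held identical values (0 identical pairs).

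Genes were named from the platform's probe annotation, and symbols were updated through a gene table of the assembly ASM3414082v1, used for names alone. This gave 22436 probe sets with 1 gene, 95 with several and 34663 with none listed. A probe set with none listed is unnamed here, and none was named from a probe set with several genes. All 17905 genes of the probe annotation were found in the gene table, and 2445 of them, on 3176 probe sets, carried an informative name. No genome build is given for the deposited table, so no coordinates are printed.

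All 12 arrays were fitted together with limma 3.58.1 (R 4.3.3), with a mean per group and the default empirical Bayes moderation, which left 8 residual degrees of freedom. The contrasts were the genotype difference at 7 d and at 11 d, its mean over both ages, its change between the ages (an interaction), and the age difference within each genotype. P-values are two-sided and were adjusted by Benjamini-Hochberg over 57194 probe sets within a contrast. A probe set passed at an adjusted p under 0.05. Differences are given on the log2 scale with the standard error (SE) of the fit, and each group mean rests on 3 arrays.

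Lists of genes were tested with limma's camera, with the preset correlation between genes of 0.01, on the probe set with the highest mean for each of 17905 genes. P-values were adjusted over the 31 lists within a contrast. A list's genes were also counted with p-values adjusted over the list alone. There were 27 pathway and family lists and 4 lists of markers of other tissues that the harvested segment could hold (root, phloem, seed storage and class I KNOX genes of the shoot meristem), and the photosynthesis list served as the marker of green leaf as well. Together the lists held 866 genes, of which 6 were on more than 1 list. The topics of the lists, the contrasts, the tests and the alternatives were fixed before the data were examined, except that leaving out an array in the list tests, the clock genes and some tests of the closing section were added later. The planned matching by gene descriptions and locus identifiers could not be used with the gene table at hand, so members were matched by gene symbols and synonyms, before any test was run.

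By a rule fixed in advance, the text names the 8 largest increases and 8 largest decreases of the genotype contrasts at each age and the 5 largest each way of the interaction and of both age contrasts, among probe sets that passed and have 1 gene with an informative name. It also names glutamine synthetase 1;2, all members of the nitrogen assimilation list, and up to 4 members with the smallest p of other lists. Genes named outside this rule are introduced as chosen after their values were seen.

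The fit was tested on simulated data with the spread of the real arrays. For the genotype difference at 7 d, over 57194 probe sets, 34.3% of changes of 0.5 (log2), 83.6% of changes of 1 and 98.5% of changes of 2 were recovered, with 6 false calls. For 11 d the shares were 41.8%, 80.6% and 100%, with 5 false calls. At each size 66 or 67 probe sets were changed, fewer than passed in the real data, so these shares and false calls do not carry over to it. In a simulation of 30 lists of 20 genes, the shifted list passed and 0 unshifted lists did. The simulated genes were independent of each other, so this does not test how correlation between the genes of a list affects its call.

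The alternatives were eBayes with trend and robust moderation, a fit of only the groups compared, a filter on the dimmest probe sets, arrays set to a common median, a new quantile normalization, array quality weights, a minimum change of 1 (log2), a single probe set per gene, leaving out each array in turn, and a block of the numbers in the sample titles at 7 d. For lists they were a correlation estimated per list, fry, which asks whether a list's genes move on balance in a single direction, and all probe sets of the listed genes. Groupings of the arrays were exchanged to see how many probe sets passed under other splits, all 10 splits for a contrast of 3 with 3 arrays and 100 drawn splits for contrasts of all arrays. Age coincides with any batch of growth or harvest, and the ordinal words in the sample titles coincide with age, so age cannot be told apart from batch or from the hour of harvest. The growth text given with every sample ends with a paragraph that assigns samples 13 to 36 to a growth chamber for 18 days, an age that no array here has, while the rest describes a greenhouse. The wild-type arrays at 11 d have the numbers 13, 14 and 15 in their titles and the mutant arrays at 11 d the numbers 1, 2 and 3, and the sources used here do not say whether these are the numbers of that paragraph. A growth condition or batch that holds a single genotype at 11 d cannot be told apart from genotype. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.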

Results

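Expression was compared between wild-type rice and the gs1;2 mutant, which lacks a cytosolic glutamine synthetase that joins ammonium to glutamate, in the basal 5 mm of the shoot at 7 and 11 d of growth with 1 mM ammonium. There were 3 arrays per genotype and age. Pearson correlations over all probe sets lay between 0.994 and 0.997 for arrays of the same group. The wild-type arrays at 11 d stood apart from the other 3 groups, with correlations of 0.978 to 0.985 with them. Mutant and wild-type arrays at 7 d correlated at 0.992 to 0.995, and arrays labelled mutant at 11 d correlated with the 7 d arrays of both genotypes at 0.987 to 0.991. The first principal component, with 48.3% of the variance, placed the wild-type arrays at 11 d between 71.9 and 84.3 and all other arrays between -39.0 and -14.7. The second, with 19.8%, set the arrays labelled mutant at 11 d apart, between -55.6 and -41.7, with all other arrays between -0.2 and 30.7.

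**Figure D1:**
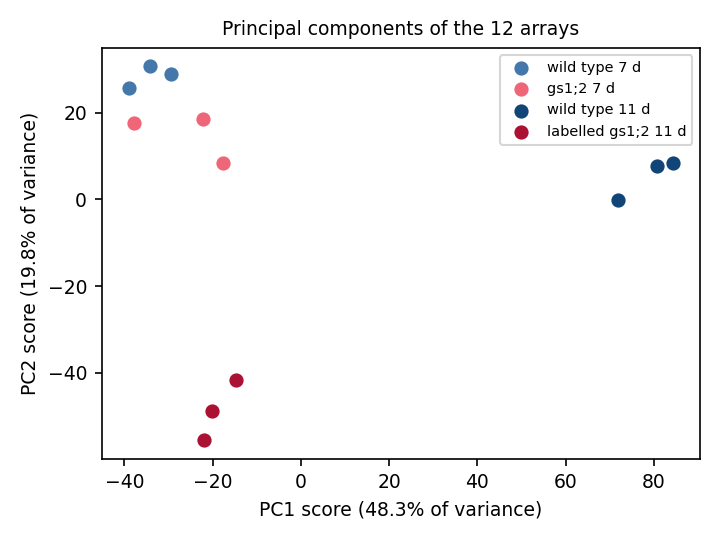
Scores of the 12 arrays on the first principal component (horizontal, 48.3% of variance) and the second (vertical, 19.8% of variance) of the log2 signals, a point per array and a colour per group. The wild-type arrays at 11 d lie between 71.9 and 84.3 on the horizontal axis, away from the arrays of the other 3 groups.

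The targeted gene, listed as GLN1-2, was read first, as a check of the labels. Its log2 signal was 12.38, 12.31 and 12.46 in the wild-type arrays at 7 d and 12.44, 12.42 and 12.50 at 11 d. The mutant arrays at 7 d gave 7.76, 7.65 and 7.80. The arrays labelled mutant at 11 d gave 8.37, 8.65 and 11.44, so in this gene the array labelled mutant 11 d replicate 3 goes against its label. Some other values of that array go with the label. Its correlations with its group are 0.995 or more. Arrays of unlike genotype at 7 d also correlated at up to 0.995, so this says little about genotype. LOC4331398 was chosen after its values were seen, with this array included, as the largest difference at both ages. The gene is at 11.00 in this array, against 10.89 in the other arrays of the group and 3.31 in wild type. A probe set with no gene listed, the sole other that was lower in the mutant by at least 2 at both ages, is at 5.04 in it, between 3.33 in the other arrays of the group and 6.71 in wild type. Whether the probes lie upstream or downstream of the insertion is not known from the labels. GS1;2 was lower in the mutant by 25.1-fold at 7 d (log2 difference -4.65, SE 0.57, adjusted p = 0.00289) and its difference at 11 d was -2.97 (SE 0.57, adjusted p = 0.00177). Without the array in doubt these were -4.65 (SE 0.09) and -3.94 (SE 0.10). Directions drawn at 11 d for the mutant rest on 3 arrays of which this is 1.

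**Figure D2:**
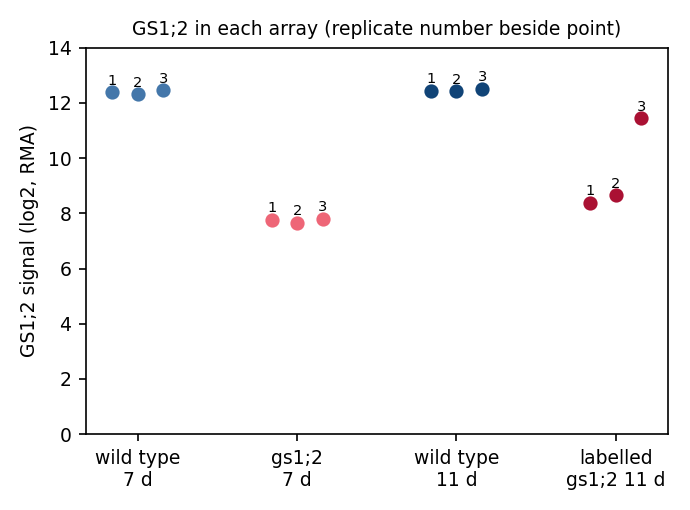
Log2 RMA signal of GS1;2 (vertical axis) in each of the 12 arrays, grouped by genotype and age, with the replicate number beside each point. The array labelled mutant 11 d replicate 3 lies at 11.44, against 8.37 and 8.65 for the other arrays of its group.

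At 7 d the comparison asks how loss of the enzyme changes the basal shoot early in growth, and few named genes differed. Besides GS1;2, NIA1, a nitrate reductase gene, rose by 1.44 (SE 0.21, adjusted p = 0.0104) and GER5, which encodes a germin-like protein, by 2.37 (SE 0.37, adjusted p = 0.0135). The SPX-domain genes SPX1 (-1.12, SE 0.14, adjusted p = 0.00379) and SPX2 (-1.13, SE 0.16, adjusted p = 0.00732), regulators of phosphate starvation responses, fell. The cellulose synthase genes CESA4 (-0.71, SE 0.11) and CESA7 (-0.71, SE 0.15), BC1 (-0.90, SE 0.16), needed for the strength of secondary walls, and the glycosyltransferase gene GT43C (-0.56, SE 0.11) also fell. These calls depended on single arrays, and the cell wall list did not pass. The chitinase gene Chia1d fell by 1.33 (SE 0.23). Further increases were NAC071 (0.97), FH10 (0.94), the iron transporter gene YSL15 (0.87), the protein kinase gene CIPK1 (0.86), AGO18 (0.79) and the arginine decarboxylase gene ADC1 (0.77).

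Of 18 nitrogen assimilation genes, 1 rose and 1 fell at 7 d, NIA1 and GS1;2, and 16 did not pass. With p-values adjusted over the list alone, 6 rose and 3 fell. The ferredoxin-dependent glutamate synthase gene Fd-GOGAT differed by 0.25, the plastidic glutamine synthetase gene GLN2 by 0.24, the cytosolic GLN1-1 by -0.23 and GLN1-3 by -0.30, and none of these passed. The NADH-dependent glutamate synthase gene GLT2 differed by 0.71 (adjusted p = 0.0931). Ammonium transporter genes ranged from -0.04 for AMT2-2 to 0.54 for AMT1 and AMT2-1, with AMT1-2 at 0.12, AMT2-3 at 0.23, AMT3-1 at 0.23, AMT3-2 at 0.07 and AMT3-3 at 0.32. The glutamate dehydrogenase genes GDH (-0.25), GDH2 (0.19) and GDH3 (-0.02) did not pass either. NIA1 is read by a pair of probe sets, and the other had group means of 4.32 to 4.53 and did not pass at either age, so the probe sets of this gene disagree.

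The list of cell cycle and replication genes was lower in the mutant at 7 d (median -0.10 over 89 genes, adjusted p = 0.0016), with adjusted p = 0.776 with an estimated correlation. In this list 1 gene rose and 2 fell (2 and 7 adjusted over the list alone), among them the origin recognition gene ORC3 (-0.53), the clamp loader gene RFC5 (-0.42) and KRP6, an inhibitor of cyclin-dependent kinases, which rose by 0.66. Cytosolic ribosomal protein genes were also lower as a list (median -0.08 over 26 genes, adjusted p = 0.00682, and adjusted p = 0.686 with an estimated correlation), although 0 of them passed singly or adjusted over the list alone. Of 86 cell wall genes, 0 rose and 5 fell (3 and 8 adjusted over the list alone), but the list did not pass (adjusted p = 0.484). ABA and dehydration genes were nearest to the threshold (adjusted p = 0.07), with the phosphatase genes PP2C35 (0.47) and PP2C69 (0.65) higher and the kinase gene SAPK7 (-0.39) lower. Among single members of other lists, GLK2, an activator of chloroplast genes, rose by 0.45 and the invertase gene CIN4 by 0.48. Without wild-type 7 d replicate 2 none of these 8 list members passed (adjusted p from 0.0945 for ORC3 to 0.165 for PP2C69).

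In all, 556 of 57194 probe sets passed at 7 d, 319 higher and 237 lower (563 and 620 with trend and robust moderation), of which 127 changed by at least 1 (log2), while 29 of 31 lists did not pass (adjusted p 0.07 to 0.999). The count was 310, 130 and 238 without wild-type 7 d replicates 1, 2 and 3, and 1556 (724 higher and 832 lower), 270 and 176 without mutant 7 d replicates 1, 2 and 3. It was 363 without wild-type 11 d replicate 2, 370 without the array labelled mutant 11 d replicate 1 and 605 without replicate 3 of that group. Of the 15 named genes other than GS1;2, 7 still passed without wild-type 7 d replicate 2, 9 without wild-type 7 d replicate 3 and 8 without mutant 7 d replicate 3. GER5 (adjusted p = 0.0719) and ADC1 (0.072) did not pass without wild-type 7 d replicate 2, nor Chia1d without mutant 7 d replicate 3 (0.0853). YSL15 and CESA7 passed in 3 of the 12 fits that leave out an array, GT43C in 4, NAC071 in 7, and BC1 and CESA4 in 9. The cell cycle list lost its call without mutant 7 d replicate 2 (adjusted p = 0.0871) and the ribosomal protein list without wild-type 7 d replicate 2 (adjusted p = 0.066). In turn, other lists passed when an array was left out. The ABA list did without wild-type 7 d replicate 1 (0.03), mutant 7 d replicate 3 (0.0298) or the array labelled mutant 11 d replicate 3 (0.0442). The jasmonate list did without wild-type 7 d replicate 2 (0.0216), mutant 7 d replicate 3 (0.0298) or that array (0.0435). The diterpenoid list did without mutant 7 d replicate 3 (0.0403) or that array (0.0158). The oxidative and detoxification list passed without mutant 7 d replicate 2 (0.0176).

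At 11 d, NIA1 was higher in the arrays labelled mutant by 3.83 (SE 0.21, adjusted p = 3.18e-07), the ammonium transporter gene AMT1-2 by 3.09 (SE 0.17, adjusted p = 2.67e-07) and APR-like1, named for its likeness to adenosine phosphosulfate reductase, by 6.94 (SE 0.41, adjusted p = 4.92e-07). GDH2, a glutamate dehydrogenase gene, fell by 3.15 (SE 0.15, adjusted p = 1.07e-07). The nicotianamine synthase genes NAS1 (2.73, SE 0.27) and NAS2 (2.23, SE 0.18), the sugar transporter genes SWEET15 (3.04, SE 0.29) and SWEET2b (2.58, SE 0.22), and RR9, a cytokinin-induced type-A response regulator gene (2.72, SE 0.16), rose. The alpha-amylase gene AMY1.3 fell by 5.16 (SE 0.43), the hexokinase gene HXK6 by 3.49 (SE 0.17) and the auxin transporter gene PIN4 by 3.38 (SE 0.20).

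All values at 11 d carry the doubt that the growth text assigns samples 13 to 36 to a chamber for 18 days and the wild-type arrays at 11 d are titled 13, 14 and 15. Another growth condition of this group cannot be told apart from genotype. For this contrast, rose and fell mean higher and lower than in these wild-type arrays, not a change within the mutant. The remaining largest decreases were PP2C45 (-4.50), HSF03 (-4.08), SAUR39 (-3.71), PCL1 (-3.68) and BBD1 (-3.56), and the remaining increases HSP17.4 (2.62) and ADI1 (2.59). Of the 18 nitrogen assimilation genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone) and 11 did not pass, and the list as a whole did not pass (adjusted p = 0.708). Besides those above, GLN2 rose by 0.97 (SE 0.08), GLT2 fell by 1.67 (SE 0.18) and GDH fell by 0.42 (SE 0.07). GLN1-1 differed by 0.22 (adjusted p = 0.07), GLN1-3 by -0.07, Fd-GOGAT by 0.17 and GDH3 by -0.12. The other ammonium transporter genes, AMT1 (0.12), AMT2-1 (0.48), AMT2-2 (-0.02), AMT2-3 (0.10), AMT3-1 (-0.16), AMT3-2 (0.80) and AMT3-3 (0.31), did not pass. Leaving out a single array would let GLN1-1 (without wild-type 11 d replicate 1, adjusted p = 0.0155), AMT3-3 (without mutant 7 d replicate 1, 0.0416) and AMT2-1 (without the array labelled mutant 11 d replicate 3, 0.0362) pass.

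Photosynthesis genes were higher in the arrays labelled mutant at 11 d, with 19 of 25 rising and 1 falling (21 and 1 adjusted over the list alone, median 0.76, list adjusted p = 2.52e-05). Examples are the protochlorophyllide oxidoreductase genes PORA (2.25, SE 0.18) and PORB (1.13, SE 0.10), the photosystem I gene PSAG (1.60, SE 0.13) and RCABP69 (1.69, SE 0.15), while the light-regulated gene LIR1, chosen after its value was seen, fell by 2.53. All 6 type-A response regulator genes rose (6 and 0 adjusted over the list alone, median 1.32, list adjusted p = 0.000208), among them RR4 (2.06), RR1 (1.44) and RR6 (1.11). Of 89 cell cycle and replication genes, 46 rose and 8 fell (52 and 10 adjusted over the list alone, median 0.29, list adjusted p = 4.2e-05), with the replication helicase genes MCM3 (0.93), MCM5 (0.94) and MCM6 (0.83) higher and KRP6 (-1.57) lower. Of 6 histone genes 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.33, list adjusted p = 0.0243), among them H2B.10 (0.69). These 4 lists each had an adjusted p = 0.69 with an estimated correlation.

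Phenylpropanoid and lignin genes were also higher, with 16 of 28 rising and 3 falling both over all genes and adjusted over the list alone (median 0.64, list adjusted p = 0.0154). They included 4CL2 (1.81), CAD2 (1.25) and the laccase gene LAC23 (1.40), whereas the laccase gene LAC7 fell by 2.59. Of 86 cell wall genes, 33 rose and 14 fell (35 and 17 adjusted over the list alone, median 0.22, list adjusted p = 0.0392), with BC1 (2.41), CSLF6 (1.93), a synthase of mixed-linkage glucan, and GT43A (1.21) higher and EXLA2 (-1.86) lower. Both lists had an adjusted p = 0.69 with an estimated correlation. The cell wall list did not pass without mutant 7 d replicate 1 (adjusted p = 0.0531) or 2 (0.0519), or without wild-type 11 d replicate 2 (0.0616) or 3 (0.0527).

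**Figure D3:**
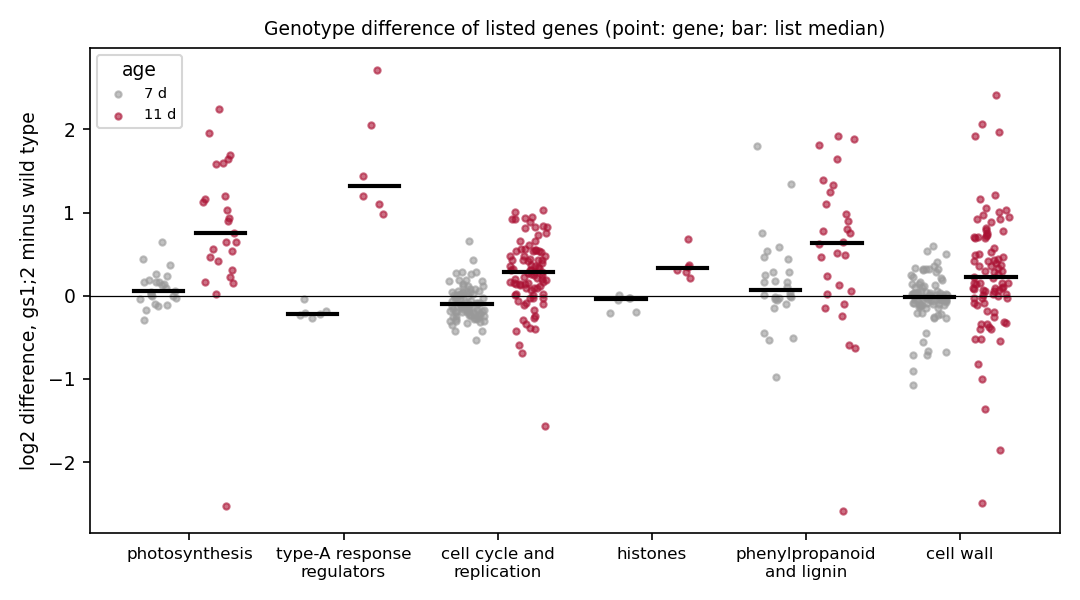
Log2 difference in signal, mutant minus wild type (vertical axis), of each gene of 6 lists, a point per gene, at 7 d (grey) and for the arrays labelled mutant at 11 d (red), with a bar at each list's median. The median of the photosynthesis list is 0.06 at 7 d and 0.76 at 11 d, and that of the type-A response regulators is -0.22 and 1.32.

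The other 25 lists did not pass at 11 d, although single members did. At this age 8724 of 17905 genes had any probe set that passed, so a count near that share does not set a list apart. The share is a rough guide, since the lists count only the probe set with the highest mean of each gene. Counts adjusted over the list alone rest on another adjustment and have no such share. The number of genes with any probe set that passed was 265 at 7 d, 5507 over both ages and 7136 for the interaction. It was 10036 for age in wild type and 2980 for age in the mutant. Of 77 ABA and dehydration genes 15 rose and 23 fell (16 and 26 adjusted over the list alone, adjusted p = 0.488), with the kinase genes SAPK9 (-2.75) and SAPK10 (-1.29) and the phosphatase gene PP2C25 (-1.80) lower. Of 9 strigolactone and tillering genes 0 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.377). These were the strigolactone receptor gene D14 (-1.93, SE 0.18), D3 (-1.10, SE 0.15), IPA1 (-0.93, SE 0.13), a regulator of tiller number, and SMAX1L (-0.80). Of 33 iron status genes 9 rose and 11 fell (10 and 11, adjusted p = 0.626), and of 53 sucrose and starch genes 11 rose and 11 fell (13 and 11, adjusted p = 0.703), with the sucrose synthase gene SUS4 (-2.20) and SWEET14 (-2.77) lower. Of 19 genes of the citrate cycle and its supply 1 rose and 5 fell (1 and 5, adjusted p = 0.392), among them the pyruvate phosphate dikinase genes PPDK2 (-1.75) and PPDKB (-1.73). Here and in the following counts, the numbers in brackets are those adjusted over the list alone.

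Of 60 auxin response genes 18 rose and 18 fell (19 and 22, adjusted p = 0.703), with the auxin transporter gene PIN5 at 1.94. Of 13 cytokinin metabolism genes 3 rose and 6 fell (3 and 6, adjusted p = 0.488), with the cytokinin oxidase gene CKX3 at 1.39 and the cytokinin activation genes LOGL3 at -1.32 and LOGL9 at -1.05. Of 16 diterpenoid phytoalexin genes 5 rose and 0 fell (5 and 0, adjusted p = 0.0755, but 0.0392 without wild-type 11 d replicate 1 and 0.001 without the array labelled mutant 11 d replicate 3). Of 47 heat shock genes 16 rose and 11 fell (18 and 11, adjusted p = 0.488), of 37 jasmonate genes 7 rose and 3 fell (8 and 5, adjusted p = 0.551), and of 21 ethylene genes 5 rose and 4 fell (7 and 5, adjusted p = 0.917). Of 14 gibberellin genes 2 rose and 5 fell (4 and 5, adjusted p = 0.582), of 20 defence genes 1 rose and 3 fell (1 and 2, adjusted p = 0.392), and of 28 oxidative and detoxification genes 9 rose and 5 fell (10 and 7, adjusted p = 0.592). Of 17 glycolysis genes 3 rose and 4 fell (4 and 7, adjusted p = 0.609), of 23 phosphate status genes 7 rose and 4 fell (7 and 4, adjusted p = 0.917), and of 62 ion and water transport genes 11 rose and 14 fell (13 and 16, adjusted p = 0.703). Of 26 ribosomal protein genes 3 rose and 0 fell (2 and 0, adjusted p = 0.244), while of 3 amino acid transporter genes 1 rose (2 and 0, adjusted p = 0.488) and of 3 nitrate transporter genes 1 rose (1 and 0, adjusted p = 0.488).

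The 4 lists of markers of other tissues did not pass at 11 d, although some members did. Of 10 root markers 4 rose and 1 fell (4 and 1, median 0.27, adjusted p = 0.172), with the endodermal regulator gene SCR1 at 1.29 and SHR1 at 0.58. Of 7 phloem markers 1 rose and 2 fell (1 and 3, adjusted p = 0.708), with the sucrose transporter gene SUT1 at -1.13. Of 11 seed storage genes 0 rose and 3 fell (0 and 3, adjusted p = 0.488), with the glutelin gene GLUA-2 at -2.12, and of 5 KNOX genes 1 rose and 2 fell (1 and 2, adjusted p = 0.703), with OSH71 at -0.52. Single arrays decided some of these calls. The root marker Lsi2 (0.0585 without wild-type 11 d replicate 2), the root marker and nitrate transporter gene NRT2.3 (0.059 without the array labelled mutant 11 d replicate 2) and the seed storage gene PROLM25 (0.129 without wild-type 11 d replicate 3) could each lose their call. So could the KNOX genes OSH3 (0.155 without the array labelled mutant 11 d replicate 2) and OSH6 (0.185 without wild-type 11 d replicate 2). Clock genes, chosen for a test after CCA1 and PCL1 had been seen among the largest changes, differed between the genotypes at 11 d alongside these lists. CCA1, a morning-phased clock gene, was higher by 1.40, and PCL1 (-3.68), PRR1 (-1.93), PRR95 (-1.32), GI (-1.16) and PRR73 (-0.37) were lower, while PRR37 (-0.10) did not pass. None of these 7 genes passed at 7 d.

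**Figure D4:**
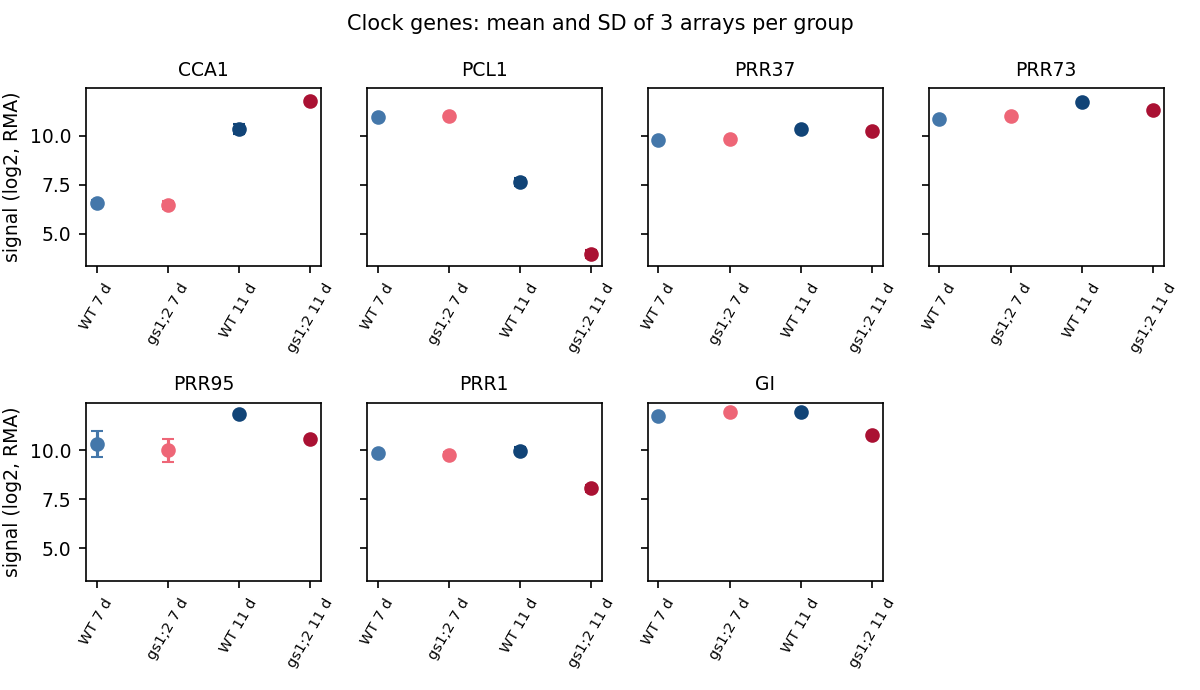
Log2 RMA signal (vertical axis) of 7 clock genes in the 4 groups, as the mean of 3 arrays with its SD, the last group being the arrays labelled mutant at 11 d. PCL1 has means of 10.95 and 10.99 in the groups at 7 d, 7.64 in wild type at 11 d and 3.96 in the arrays labelled mutant at 11 d.

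In all, 14820 probe sets passed at 11 d, 7333 higher and 7487 lower, and 2465 of them changed by at least 1 (log2), 1004 higher and 1461 lower. The balance was 6099 and 8139 with arrays set to a common median and turned to 7696 and 7215 with a new quantile normalization. Without the array labelled mutant 11 d replicate 3 the count was 13475, of which 12649 were shared. The median, the mean and the test differed in sign for 8 lists at 7 d, among them nitrogen assimilation (median 0.21, mean -0.03, test upward), and for 7 lists at 11 d, among them iron status (median -0.07, mean 0.07, test downward), and 0 of these lists passed. Between the genotype contrasts at the 2 ages, which share no arrays, 309 probe sets passed in both. Of these, 128 were higher at both ages, against 40.9 from independent lists of these sizes, 51 were lower at both against 31.0, and 130 went in opposite directions against 72.2. Both contrasts use the same estimate of spread for a probe set, so their calls are not independent. The numbers from independent lists are therefore not a measure of chance. The differences at the ages correlated at -0.0435 over all probe sets.

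Averaged over both ages, photosynthesis genes were higher in the mutant, with 18 of 25 rising and 1 falling (20 and 1, list adjusted p = 1.99e-06), for example PORA by 1.19 (SE 0.13) and RCABP69 by 0.97 (SE 0.10). All 6 type-A response regulator genes rose (6 and 0, list adjusted p = 0.000316), RR9 by 1.25 (SE 0.11), as did 11 of 28 phenylpropanoid and lignin genes while 1 fell (12 and 1, list adjusted p = 0.00936), among them 4CL2 by 1.13 and CAD6 by 0.58. Each of these 3 lists had an adjusted p = 0.685 with an estimated correlation. Of 89 cell cycle genes 23 rose and 5 fell (32 and 6, list adjusted p = 0.0157, and adjusted p = 0.732 with an estimated correlation), MCM5 by 0.39. These averages do not stand for a difference at each age. The cell cycle list was lower in the mutant at 7 d (list adjusted p = 0.0016) and higher at 11 d (4.2e-05). The type-A list pointed downward at 7 d without passing (list adjusted p = 0.112) and upward at 11 d (0.000208), with RR9 at -0.21 and 2.72. Of 16 diterpenoid phytoalexin genes 6 rose and 0 fell (6 and 0, list adjusted p = 0.0184, and adjusted p = 0.717 with an estimated correlation), among them the cyclases CPS2 (1.54, SE 0.40) and CPS4 (1.21, SE 0.31) and the cytochromes P450 CYP701A8 (1.55, SE 0.37) and CYP99A3 (1.13, SE 0.25). The largest changes, named after the values were seen, were APR-like1 (3.06), NIA1 (2.64), GER5 (2.26), DREB1G (1.62) and AMT1-2 (1.60) upward, and GS1;2 (-3.81), AMY1.3 (-2.36), PP2C45 (-2.30), HSF03 (-2.17) and HXK6 (-1.87) downward.

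Of the nitrogen assimilation genes 6 rose and 4 fell over both ages (6 and 4), with Fd-GOGAT (0.21), AMT3-3 (0.32), AMT2-1 (0.51), GLN2 (0.60), GLT2 (-0.48), GDH (-0.34) and GDH2 (-1.48) among those that passed. In all 9071 probe sets passed, 4247 higher and 4824 lower, and 8837 passed without the array labelled mutant 11 d replicate 3, of which 8016 were shared. Without mutant 7 d replicate 2, the diterpenoid list (adjusted p = 0.116) and the phenylpropanoid list (0.0725) did not pass, while the cell wall list passed without mutant 7 d replicate 1 (0.0387) or wild-type 11 d replicate 1 (0.0282). Leaving out an array raised the adjusted p to as much as 0.0536 for Fd-GOGAT (the array labelled mutant 11 d replicate 1), 0.0608 for GLT2 (wild-type 7 d replicate 2), 0.0742 for AMT3-3 (wild-type 11 d replicate 3) and 0.0787 for AMT2-1 (the array labelled mutant 11 d replicate 1). The other 26 lists had adjusted p from 0.0991 to 0.987.

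The interaction tests whether the genotype difference at 11 d departs, in either direction, from that at 7 d. It shares arrays with the genotype contrast at 11 d, and the changes of both correlated at 0.903 over all probe sets. Calls in both are therefore not separate findings. Of the 18 nitrogen assimilation genes, 4 changed upward between the ages and 2 downward (4 and 2): AMT1-2 (2.96, SE 0.24), NIA1 (2.39, SE 0.30), GLN2 (0.73, SE 0.11) and GLN1-1 (0.45, SE 0.11), and GDH2 (-3.34, SE 0.21) and GLT2 (-2.39, SE 0.26). The difference in GS1;2 was 1.68 (adjusted p = 0.174) and, without the array labelled mutant 11 d replicate 3, 0.71 (adjusted p = 0.00316). Cell cycle and replication genes moved upward, 40 against 8 downward of 89 (48 and 8, list adjusted p = 2.54e-06), with RPA70b (1.44), PCNA (1.12) and MCM3 (1.11), while KRP6 moved by -2.23. All 6 type-A response regulator genes (6 and 0, list adjusted p = 0.000153), 12 of 25 photosynthesis genes against 1 (13 and 1, list adjusted p = 0.000625) and 5 of 6 histone genes (6 and 0, list adjusted p = 0.0178) moved upward. So did 28 of 86 cell wall genes against 14 (31 and 14, list adjusted p = 0.0336), such as BC1 (3.31) and CSLF6 (1.99), and 3 of 26 ribosomal protein genes (3 and 0, list adjusted p = 0.027), such as rps20 (0.59). Each of these 6 lists had an adjusted p = 0.638 with an estimated correlation.

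In total 11780 probe sets passed the interaction, 5645 upward and 6135 downward (6108 and 5935 with a new quantile normalization), and 10935 without the array labelled mutant 11 d replicate 3, of which 10288 were shared. The cell wall list did not pass without wild-type 7 d replicate 3 (adjusted p = 0.0509) or mutant 7 d replicate 1 (0.133), nor the ribosomal protein list without wild-type 7 d replicate 2 (0.0633) or mutant 7 d replicate 3 (0.0559). The remaining 25 lists had adjusted p from 0.0527 to 0.931. The lowest of these, the phenylpropanoid list, passed without wild-type 7 d replicate 1 (0.0407), mutant 7 d replicate 2 (0.0211), wild-type 11 d replicates 1 (0.0201) or 2 (0.047), or the array labelled mutant 11 d replicate 3 (0.0218). The diterpenoid list passed without the array labelled mutant 11 d replicate 3 (0.0335).

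In wild type, the comparison of 11 d with 7 d holds the course of growth together with any difference in batch or hour of harvest. Clock genes changed strongly in it, CCA1 by 3.79 and PCL1 by -3.31, so the changes cannot be read as growth alone. This contrast, the genotype contrast at 11 d and the interaction all use the wild-type arrays at 11 d. Of 11025 probe sets that passed here and for genotype at 11 d, 10807 went in opposite directions. A shift of these wild-type arrays alone can appear in all of these contrasts, so their calls are not separate findings. RR9 had means of 8.95 and 8.74 at 7 d, 6.87 in wild type at 11 d and 9.59 in the arrays labelled mutant. Replication genes fell with age, 58 of 89 cell cycle genes against 10 that rose (59 and 12 adjusted over the list alone, list adjusted p = 6.76e-06, and adjusted p = 0.486 with an estimated correlation), with ORC3 at -1.24 (SE 0.09), RPA70b at -1.26 (SE 0.11) and MCM3 at -0.97 (SE 0.09). Of 26 ribosomal protein genes 15 fell and 0 rose (17 and 0, list adjusted p = 0.000244), with rpl5 at -1.06, and all 6 type-A response regulator genes fell (6 and 0, list adjusted p = 0.00155), with RR9 at -2.08 and RR5 at -1.68. Both lists had an adjusted p = 0.39 with an estimated correlation. All 6 histone genes fell (6 and 0, list adjusted p = 0.0195, and adjusted p = 0.477 with an estimated correlation). Of 77 ABA and dehydration genes 36 rose and 10 fell (39 and 12, list adjusted p = 0.0207, and adjusted p = 0.39 with an estimated correlation), with PP2C61 at 2.63 and PP2C25 at 1.36.

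The largest increases with age in wild type were the chitinase genes Cht4 (4.47, SE 0.57) and chia4a (4.12, SE 0.30), AMY1.3 (4.42, SE 0.43), SAUR39 (3.87, SE 0.27) and the dehydrin gene RAB21 (3.85, SE 0.38). The largest decreases were APR-like1 (-4.75, SE 0.41), PCL1 (-3.31, SE 0.13), JAZ13 (-2.77), the peroxidase gene PRX112 (-2.67) and FBPase (-2.45). Of the nitrogen assimilation genes 2 rose and 5 fell (2 and 6), with GDH2 at 3.00, GLN2 at -1.32 and NIA1 at -1.65, and SUS4 (2.24), SWEET14 (2.75) and D14 (1.82) rose. Of the clock genes, CCA1 (3.79), PRR95 (1.54), PRR73 (0.86) and PRR37 (0.55) also rose with age in wild type, while PRR1 (0.14) and GI (0.18) did not pass. In total 18208 probe sets passed, 8579 higher and 9629 lower at 11 d (9041 and 8458 with arrays set to a common median, and 1811 and 966 among changes of at least 1), and 26 of 31 lists did not pass (adjusted p 0.0766 to 0.978). Leaving out wild-type 11 d replicate 2 let the defence list (0.0345) and the auxin list (0.0489) pass, and leaving out wild-type 7 d replicate 3 the photosynthesis list (0.0307) and the auxin list (0.0486).

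In the mutant, the arrays labelled mutant at 11 d were set against the mutant arrays at 7 d. This comparison also holds any difference in batch or hour of harvest. Of 19 genes of the citrate cycle and its supply, 4 fell and 1 rose (7 and 1, list adjusted p = 0.00158, and adjusted p = 0.105 with an estimated correlation), among them the succinate dehydrogenase genes SDH3-1 (-0.48) and SDH3-2 (-0.28) and the pyruvate dehydrogenase gene PDHE1-B (-0.40). The malic enzyme gene ME6 rose by 0.40. Of 47 heat shock genes 11 rose and 2 fell (17 and 2, list adjusted p = 0.00912, and adjusted p = 0.616 with an estimated correlation), with HSF24 at 2.07, HSP81-1 at 0.79 and HSF03 at -3.44. Of 28 phenylpropanoid and lignin genes 8 rose and 1 fell (12 and 2, list adjusted p = 0.0148, and adjusted p = 0.621 with an estimated correlation), PAL06 by 1.68 and 4CL-3 by 1.47. The phenylpropanoid list did not pass without mutant 7 d replicate 1 (adjusted p = 0.0731), nor SDH3-2 without mutant 7 d replicate 3 (0.0613) or the arrays labelled mutant 11 d replicate 1 (0.0519) or 2 (0.0739), nor ME6 without replicate 2 (0.0563) or 3 (0.0569) of that group.

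Here the largest increases were the clock gene CCA1 (5.27, SE 0.14), Cht4 (4.40), chia4a (4.14), APR-like1 (3.11 on another of its probe sets, and 3.01 on that of the values above) and AMT1-2 (2.82), and the largest decreases PCL1 (-7.03, SE 0.13), SAPK9 (-3.62), HSF03 (-3.44), BBD1 (-3.34) and the iron transporter gene VIT1.2 (-2.77). Of the other clock genes, PRR37 (0.41) and PRR73 (0.35) rose, PRR1 (-1.73) and GI (-1.15) fell, and PRR95 (0.56) did not pass. Of the nitrogen assimilation genes 1 rose and 5 fell (4 and 6), with GLN2 at -0.59, GLT2 at -1.21 and Fd-GOGAT at -0.48, and NAS1 (2.81), NAS2 (2.07) and PSAG (2.50) rose. In total 4846 probe sets passed, 2067 higher and 2779 lower at 11 d (423 and 330 among changes of at least 1), and 3725 without the array labelled mutant 11 d replicate 3, of which 3362 were shared. The photosynthesis and type-A response regulator lists had adjusted p = 0.0501 and the other lists that did not pass had higher values, up to 0.997. The photosynthesis list passed without wild-type 7 d replicates 1 (0.0281) or 3 (0.016), mutant 7 d replicate 2 (0.0316), wild-type 11 d replicate 3 (0.045), or the arrays labelled mutant 11 d replicates 2 (0.0176) or 3 (0.0494). The type-A list passed without wild-type 7 d replicate 2 (0.0477), wild-type 11 d replicates 1 (0.0429) or 3 (0.045), or the arrays labelled mutant 11 d replicates 1 (0.0415) or 2 (0.0195). So did the diterpenoid list without mutant 7 d replicate 2 (0.0247) or the array labelled mutant 11 d replicate 3 (4.34e-05). The ribosomal protein list passed without mutant 7 d replicate 3 (0.0219) or the array labelled mutant 11 d replicate 1 (0.0463). The age contrasts of the genotypes, which share no arrays, had 3052 probe sets in common, 2263 in the same direction (816 higher and 1447 lower, against 310 and 468 from independent lists). Opposite directions were seen for 789 (against 765), and the correlation over all probe sets was 0.18. These contrasts also share the estimate of spread for a probe set, so the numbers from independent lists are not a measure of chance.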

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

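The clock genes were chosen after CCA1 and PCL1 had been seen among the largest changes, so the test of the phase of day rests on the other 5, and the values of the clock genes without the array labelled mutant 11 d replicate 3 were also added after the results were seen.

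The genotype difference changed between the ages for 11780 probe sets. Lists that changed were cell cycle and replication (adjusted p = 2.54e-06), type-A response regulators (0.000153), photosynthesis (0.000625), histones (0.0178), ribosomal proteins (0.027) and cell wall (0.0336). All 6 had an adjusted p = 0.638 with an estimated correlation. Among the genes named for the size of their change in the interaction or in the genotype contrast at either age, or as nitrogen assimilation genes, upward changes were APR-like1 (7.76), BC1 (3.313), AMT1-2 (2.963), RR9 (2.928), SWEET15 (2.905), NAS1 (2.872), ADI1 (2.491), HSP17.4 (2.44) and NIA1 (2.387). Smaller upward changes among them were CESA7 (1.746), CESA4 (1.488), SPX2 (0.935), SPX1 (0.856), GT43C (0.848), GLN2 (0.729) and GLN1-1 (0.446). The downward changes among them were CIPK1 (-0.587), AGO18 (-1.262), YSL15 (-1.78), GLT2 (-2.385), PIN4 (-3.199), HXK6 (-3.254), GDH2 (-3.338), BBD1 (-3.435), PCL1 (-3.728), HSF03 (-3.808), SAUR39 (-4.357), PP2C45 (-4.408) and AMY1.3 (-5.594). Of these genes, BC1 (-0.90 and 2.41), CESA4 (-0.71 and 0.78), CESA7 (-0.71 and 1.03), AGO18 (0.79 and -0.47) and YSL15 (0.87 and -0.91) passed at both 7 and 11 d with opposite signs. So did the cell cycle genes KRP6 (0.66 and -1.57), ORC3 (-0.53 and 0.57) and RFC5 (-0.42 and 0.53). Most of these calls at 7 d depended on single arrays. Of the 12 fits that leave out an array, RFC5 passed at 7 d in 2, KRP6, CESA7 and YSL15 in 3, ORC3 in 8, BC1 and CESA4 in 9, and AGO18 in all 12.

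Exchanging arrays between groups asks how many probe sets pass under other splits of the same arrays. With 3 arrays per group there are 10 splits, too few for a share under 0.05, and the real split gave the highest count, 1 of 10 splits, in each contrast of this kind. The counts were 556 against a highest other of 0 for genotype at 7 d, 14820 against 2 for genotype at 11 d, 18208 against 0 for age in wild type and 4846 against 1 for age in the mutant. Among 100 drawn splits, the real one included, only the real split reached its count of 11780 for the interaction (highest other 9071). For genotype over both ages 4 splits, the real one included, gave 9071 or more, so some exchanged splits exceeded the real count. The highest other for genotype over both ages, 11780, is the split that exchanges the genotypes at 11 d alone, which is the interaction itself. Further exchanged splits gave 9985 and 9576.

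That the wild-type arrays at 11 d stood apart was set against technical readings. After arrays were set to a common median, 14238 probe sets passed at 11 d, the lower of the counts from a pair of scalings. The medians of the deposited values were already close, so rescaling could change little. The differences left in the medians therefore do not account for the count at 11 d. A distortion made by the original normalization cannot be excluded by this test and stays open. A single aberrant wild-type array is not favoured, since at least 11606 passed whichever wild-type array at 11 d was left out. Different shares of root and of green leaf could contribute and stay open, with a root marker median of 0.274 at 11 d (quartiles 0.209 and 0.728) and a photosynthesis median of 0.758. Another growth condition of the wild-type plants at 11 d, whose titles hold the numbers 13 to 15 and for whose samples the growth text may name a chamber and 18 days, also stays open, as no value tested here separates it from genotype. A harvest at another phase of the day may also contribute, since 3 of 5 clock genes passed with a change of at least 1 at 11 d and 0 at 7 d, and PRR1 (-1.99), PRR95 (-1.34) and GI (-1.19) kept their calls without the array labelled mutant 11 d replicate 3.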

How the results depend on the processing

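Leaving out an array in the list tests was added after the data were seen, while the other alternatives were fixed in advance.

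When single arrays were left out, the count of 556 at 7 d was the least stable. It became 1183 with trend and robust moderation, 249 with only the groups compared, 321 with array quality weights, 337 with a single probe set per gene, 133 with the block of title numbers and 127 with a minimum change of 1 (log2), and ranged from 130 to 1556 when an array was left out. A minimum change of 1 left 2465 at 11 d, 559 over both ages, 3133 for the interaction, 2777 for age in wild type (1811 higher and 966 lower) and 753 for age in the mutant (423 higher and 330 lower). A single probe set per gene tests fewer probe sets and left 9596 at 11 d and 10689 for age in wild type. With only the groups compared, 3172 passed for age in the mutant, where the fit has fewer residual degrees of freedom. When an array was left out, counts ranged from 11606 to 15212 at 11 d, 6852 to 9150 over both ages, 9610 to 12187 for the interaction, 15302 to 18576 for age in wild type and 3307 to 4794 for age in the mutant. The cause of the other changes was not tested.

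The block of title numbers at 7 d left 5 residual degrees of freedom, and the difference in GS1;2 was then -4.679 (adjusted p = 0.0779). Only the numbers 8 and 9 occur in both genotypes, so the genotype difference of this fit rests on the arrays with these numbers. Residuals of arrays sharing a number correlated at 0.047 and 0.051, and those of arrays with unlike numbers at 0.056 and -0.139. These few values show no pairing by number but cannot exclude it.

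Of 31 lists, 2 passed at 7 d, 6 at 11 d, 5 over both ages, 6 for the interaction, 5 for age in wild type and 3 for age in the mutant. With an estimated correlation these became 0, 0, 0, 0, 0 and 0, with fry 1, 22, 18, 21, 24 and 11, and with all probe sets of the listed genes 9, 9, 9, 7, 12 and 7. When an array was left out the ranges were 2 to 5, 5 to 7, 3 to 6, 5 to 8, 5 to 7 and 2 to 5. Of the 80 named or listed genes other than GS1;2 that passed at 11 d, 75 passed in all 12 fits that left out an array, against 6 of 24 at 7 d. GS1;2 passed in all 12 at both ages. No named gene reversed its sign with a call under any alternative.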

Other observations

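The tests of a swap and of a wrong label, the probe sets that differ by at least 2 (log2) at both ages, the probe sets that set a single array apart and the diterpenoid values per array were all chosen after the results were seen.

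A small set of probe sets differed by at least 2 (log2) between the genotypes at both ages. There were 15, of which 13 were higher in the mutant, 7 of them with a gene listed, and 2 lower, GS1;2 and a probe set with no gene listed (-3.13 at 7 d and -2.81 at 11 d). The gene LOC4331398 rose from a mean of 3.00 in wild type to 10.51 in the mutant at 7 d and from 3.31 to 10.93 at 11 d, differences of 7.52 (SE 0.12, adjusted p = 8.15e-12) and 7.62 (adjusted p = 6.96e-12). A second probe set of this gene differed by 6.83 and 7.60. The other genes listed were GER5 (2.37 and 2.14), LOC4329228 (3.41 and 2.64), LOC4340325 (3.39 and 4.95), LOC4350282 (2.93 and 3.41) and LOC4328903 (2.80 and 2.88), and probe sets with no gene listed differed by up to 6.29 at 7 d and 5.63 at 11 d. In the array labelled mutant 11 d replicate 3, the 13 higher probe sets differed from the other arrays of the group by a median of 0.02 (-0.76 to 1.04). They were picked with this array in the fit, so a probe set in which it lay near wild type would tend to be left out. Picked without it at 11 d, 14 higher probe sets had moved a median share of 0.042 of the distance to wild type in it (highest 0.803). Both lower probe sets of the 15 were nearer to wild type in this array, GS1;2 at 11.44 and the other at 5.04, against 3.33 in the other arrays of the group and 6.71 in wild type.

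Diterpenoid phytoalexin genes varied between arrays of the same group. The median of the 16 listed genes, relative to the wild-type mean at 7 d, was 0.38, 0.73 and 0.27 in the mutant arrays at 7 d, and 1.14, 2.02 and 0.12 in the arrays labelled mutant at 11 d, the last value being that of replicate 3. In wild type at 11 d it was 0.35, -0.07 and -0.02. Without the array labelled mutant 11 d replicate 3 the list passed in the genotype contrasts at 7 d (adjusted p = 0.0158) and at 11 d (0.001). With all arrays and an estimated correlation, which is 0.486 for this list, these were 0.837 and 0.69. In that array 43 probe sets differed by at least 2 from the mean of the other arrays of its group, 25 lower and 18 higher, the lower ones including CPS2 (-2.55), CYP701A8 (-2.33), CYP99A2 (-2.26), DTS2 (-2.25) and CPS4 (-2.04). The gene JAZ2, a repressor of jasmonate responses, was higher there by 5.85, while JAZ13 of the same family was lower (-2.14).

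Slower development of the mutant would make its arrays at 11 d resemble younger wild-type plants, and could explain why they lay near the 7 d arrays. Under that reading, age changes in the mutant would be smaller copies of those in wild type. Of the probe sets that passed for age in wild type, 58.08% moved in the same direction in the mutant. The median ratio was 0.077 and the slope 0.114. Among those that passed in both age contrasts, 2263 went in the same direction. Opposite directions were seen for 789, against 765 from lists taken as independent. With changes this small in the mutant, noise can set the direction of many probe sets. Both age contrasts also hold any difference in batch or hour of harvest. The test therefore does not decide for or against slower development.

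The GS1;2 signal of the array labelled mutant 11 d replicate 3, at 11.44, lay between the genotypes. Tissue like that of the wild-type arrays at 11 d, mixed into the sample, would pull probe sets higher in those arrays in proportion. The median wild-type share over 361 such probe sets was 0.0356 (quartiles 0.0045 and 0.082), which speaks against tissue of that kind. Wild-type tissue of another growth condition or hour of harvest need not carry these signals and was not tested. An exchange with a wild-type array of the series is not favoured, since the lowest wild-type GS1;2 signal was 12.31. A working copy of the gene could restore wild-type expression in part, and the median share of restoration was 0.18 over 172 probe sets (quartiles -0.066 and 0.408), which leaves this open. A wild-type sample under a wrong label is not favoured, since over 14 probe sets at least 2 (log2) higher in the mutant at both ages, picked without this array at 11 d, it had moved a median share of 0.042 of the distance to wild type (quartiles -0.015 and 0.144, highest 0.803).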
